A study of Mus musculus with 15 samples.

How the data were processed

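RNA abundance was measured in primary male mouse embryonic fibroblasts on 15 Affymetrix mouse expression arrays. The arrays fell into 5 groups of 3. Fibroblasts with floxed Hdac1 carried a virus for Cre-ERT2, a Cre recombinase that tamoxifen switches on, and a virus for a micro-RNA that was directed against Hdac2 or scrambled. Ethanol-treated cells with the scrambled micro-RNA served as control. Tamoxifen at 200 nM gave the Hdac1 knockout (KO), the micro-RNA against Hdac2 gave the knockdown (Kd), and the combination gave cells with both. The fifth group was made of cells with intact Hdac1 (+/+) and tamoxifen; which viruses these cells carried is not given in the sources used here. Total RNA was column-purified and labelled with biotin by in vitro transcription, per the labels' protocols.

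The deposited table held linear intensities for 45037 probe sets, 1 value per probe set and array. How the authors summarised, background-corrected and scaled these intensities is not given in the sources used here. Array medians ran from 24.1 to 30.7 and the 75th percentiles from 414 to 531, so that the table was on 1 common scale without identical distributions. No pair of arrays held identical values. A gene annotation table for the array gave 1 symbol to 34945 probe sets, several symbols to 932 and none to 9160; probe sets with several symbols or none were left out. The Entrez IDs of 34741 probe sets were found in a RefSeq gene table, which changed 0 symbols. Symbols of the naming rule without a tested probe set were not analysed here.

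Values were transformed to log2(intensity + 16), and every fold change is on that scale, which understates changes of dim genes. A probe set was kept when it exceeded its array's 40th percentile on at least 3 arrays, and the probe set with the highest mean stood for its gene, which left 13373 genes of 18193 symbols. limma 3.58.1 in R 4.3.3 was fitted to all 15 arrays with 1 coefficient per group (lmFit, contrasts.fit, eBayes), with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. The comparisons were KO, Kd and both against control, both against each single perturbation, the interaction of deletion and knockdown (the effect of deletion in knockdown cells minus its effect in control cells), and +/+ cells with tamoxifen against control. All p-values printed are limma's or camera's adjusted values. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.0868, and 0.123 for the interaction.

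Gene lists, 32 in all, were written down before the data were examined. Of 749 list entries 605 were tested. Some genes, such as Cdkn1c, are on several lists, so list results are not independent of each other. Each list was tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists, and again with a correlation estimated from the data. With the estimated correlation 0 lists passed in any comparison; the smallest adjusted p was 0.37 for KO, 0.538 for Kd, 0.474 for both, 0.484 for both against Kd, 0.46 for both against KO, 0.453 for the interaction and 0.902 for +/+ cells. With the preset correlation 11, 10, 14, 12, 10, 12 and 7 lists passed, in that order.

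Named genes were also chosen by a rule fixed before the data were examined: 3 class I deacetylases; a set of cell cycle genes; for each comparison with control the 6 highest and 6 lowest genes past the threshold whose arrays did not overlap, and the 3 highest and 3 lowest for the other comparisons; up to 4 members per list with the largest absolute change; and Y-linked genes. Clone and model names were passed over. List members past the threshold are given in order of size; not every member that the rule allows is printed.

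The procedure was tested on simulated data for KO against control with 13373 genes in 5 runs. It called 14.8% of genes changed by a log2 value of 0.25, 76% at 0.5, 99.2% at 1 and 99.2% at 2, and 3.77% of its calls were unchanged genes. A list shifted by 0.3 was called in 5 of 5 runs, and 0.2 other lists per run. The simulated genes varied independently of each other, so these list rates do not test the preset correlation.

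Alternatives fixed beforehand were a trended and robust eBayes, only the compared groups in the model, the replicate number as a block, no filter or a stricter one at the 60th percentile, the mean of a gene's probe sets, omission of _x_at and _s_at probe sets, quantile normalization, centring of each array on its median, arrayWeights, a pseudocount of 1, each array left out in turn and, for 2 comparisons, +/+ cells with tamoxifen as control. Overlaps between comparisons that share control arrays were set beside simulated unchanged groups and beside the overlap of independent lists. The control group of 3 arrays cannot be split into parts of 2, so part of such an overlap may come from shared controls.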

Results

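Genome-wide expression was measured in mouse embryonic fibroblasts that lacked histone deacetylase 1, had reduced histone deacetylase 2, or both. Hdac1 and Hdac2 are closely related enzymes that remove acetyl groups from histones. The 15 arrays comprised control cells, Hdac1 knockout (KO) cells, Hdac2 knockdown (Kd) cells, cells with both perturbations and Hdac1 +/+ cells with tamoxifen, with n = 3 arrays in each. KO cells, cells with both and +/+ cells had received 200 nM tamoxifen, whereas control and Kd cells had received ethanol. Median intensities of the arrays ran from 24.1 to 30.7. The Y-linked gene Kdm5d was measured at 780 ± 37 in control, 826 ± 39.1 in KO, 712 ± 13.4 in Kd, 833 ± 58 with both and 711 ± 78.5 in +/+ cells (mean intensity ± SD, n = 3).

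The targeted genes followed the labels. Hdac1 had an intensity of 3557 ± 101 in control, 3855 ± 105 in Kd and 4472 ± 311 in +/+ cells, against 161 ± 19.8 in KO and 156 ± 48.6 with both (SD, n = 3). This was a log2 fold change of -4.34 ± 0.15 in KO (SE; adjusted p = 4.39e-11). Hdac2 went from 7051 ± 449 in control to 958 ± 62.1 in Kd and 1025 ± 9.88 with both, log2 fold changes of -2.86 ± 0.07 (adjusted p = 7.75e-13) and -2.76 ± 0.07. A further Hdac2 probe set fell from 3768 ± 148 to 523 ± 28.9 in Kd, and another lay between 20.1 and 24.7 in all groups. Hdac2 in KO cells was at 7167 ± 617 (log2 fold change 0.02, adjusted p = 0.872) and Hdac1 in Kd cells differed from control by 0.12 (adjusted p = 0.718). Hdac3, the related deacetylase of a separate complex, was at 1316 ± 73.8 in control and 1468 ± 92.4 with both (log2 fold change 0.16, adjusted p = 0.063). Whether the Hdac1 probe set lies within the deleted part of the gene is not given in the sources used here.

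**Figure D1:**
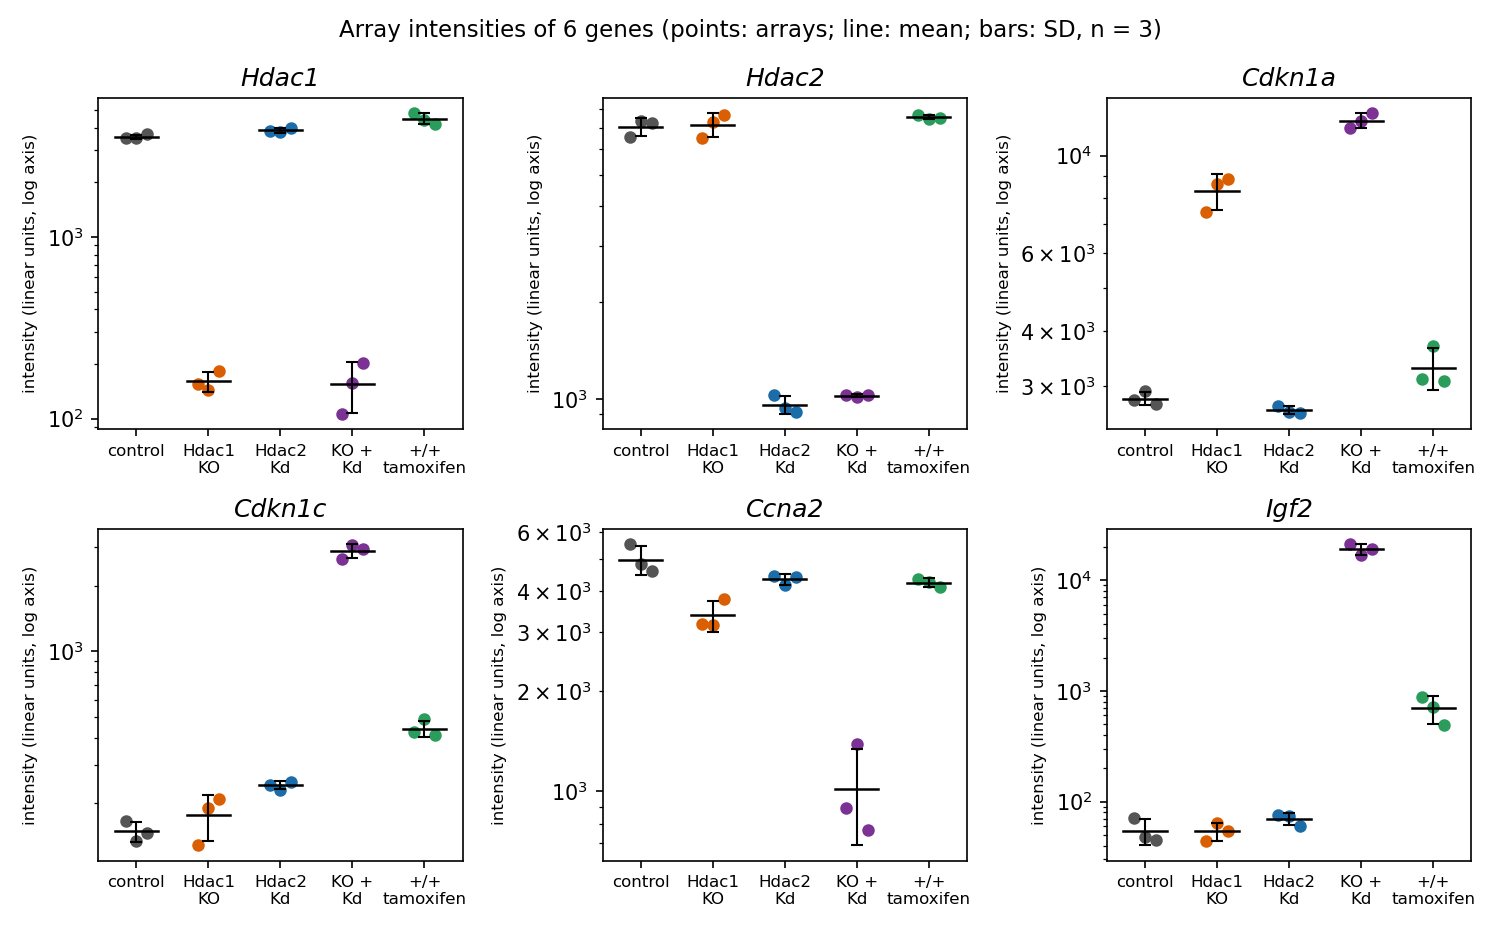
Intensity of 6 genes on each array (linear units on a log axis) by group; points are arrays, lines are means and bars are SD (n = 3). Hdac1 was low in the 6 arrays with deletion and Hdac2 in the 6 with knockdown, while Cdkn1c and Igf2 were highest with both perturbations.

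Hdac1 KO cells had higher p53 target genes and lower genes of DNA replication and mitosis than control cells, which had not received tamoxifen. Of 28 tested targets of p53, a transcription factor activated by stress and DNA damage, 24 rose and 0 fell (25 and 0 adjusted over the list alone; median log2 fold change 0.67). Cdkn1a, which encodes the cell cycle inhibitor p21, went from 2811 ± 98.5 to 8308 ± 766 (SD, n = 3; log2 fold change 1.55 ± 0.08 SE, adjusted p = 6.97e-09). Mdm2, which encodes the ubiquitin ligase of p53, rose by 1.41 ± 0.07, and Pmaip1, Eda2r and Trp53inp1 rose by 1.81, 1.7 and 1.49. Of 47 genes of DNA replication and S phase 33 fell and 1 rose (37 and 1 adjusted over the list alone; median -0.38), among them Tk1 (-0.71), Pole (-0.7) and Gins1 (-0.67). Of 49 genes of mitosis and G2 22 fell and 0 rose (32 and 0 adjusted over the list alone; median -0.43), with Spc24 at -0.94, Cdc25c at -0.85 and Birc5 at -0.69. The adjusted p was 1.92e-15 for p53 targets, 2.35e-23 for replication and 7.63e-23 for mitosis, and adjusted p = 0.37 for each with an estimated correlation. After quantile normalization the counts higher and lower were 22 and 2, 0 and 41, and 0 and 42.

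Other groups also moved in KO cells. Of 27 lysosome and autophagy genes 23 rose and 0 fell (24 and 0 adjusted over the list alone; adjusted p = 2.11e-09), including Neu1 (1.01), Ctsd (0.81) and Glb1 (0.64). Of 20 immediate early genes, which respond to growth factors and stress within minutes, 14 rose and 0 fell (16 and 0 adjusted over the list alone; adjusted p = 2.67e-06), with Btg2 at 1.21, Nr4a1 at 1.15 and Dusp1 at 1.1. With an estimated correlation the adjusted p was 0.37 for both groups. The list of contractile and actin cytoskeleton genes, here called contractile genes, had 14 higher and 0 lower of 20 (15 and 0 adjusted over the list alone, adjusted p = 5.35e-06, and adjusted p = 0.46 with an estimated correlation). Ankrd1 (0.84) and Ccn2 (0.62) were among the higher members of this list. Of 12 genes known to rise with HDAC inhibitors 8 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.00596, and adjusted p = 0.465 with an estimated correlation), including the metallothionein Mt1 (0.7). Of 9 pericyte and smooth muscle markers 5 rose and 0 fell (6 and 0 adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.37 with an estimated correlation), led by Notch3 (1.3) and Mcam (1.09). Without _x_at and _s_at probe sets Notch3 was at 0.21 (adjusted p = 0.176). Cholesterol synthesis genes had 11 higher and 0 lower of 20 (13 and 0 adjusted over the list alone; adjusted p = 0.000828, and adjusted p = 0.688 with an estimated correlation), led by Tm7sf2 (0.94) and Nsdhl (0.56). Linker and replication-independent histones had 1 higher (H1f2, 0.89) and 3 lower (H2ax at -0.51 and the H2A.Z genes H2az1 at -0.24 and H2az2 at -0.3) of 10 (2 and 6 adjusted over the list alone; adjusted p = 0.00903, and adjusted p = 0.37 with an estimated correlation). H2az1 kept its call in 8 of 18 alternatives and H2az2 in 14. HDAC complex members had 1 higher and 5 lower of 33 (1 and 5 adjusted over the list alone; adjusted p = 0.00828, and adjusted p = 0.868 with an estimated correlation), but the deleted Hdac1 was among the 5, beside Chd3 (-0.49). Without Hdac1 and Hdac2 the list did not pass (adjusted p = 0.0517, and adjusted p = 0.898 with an estimated correlation; median 0.03).

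Single genes changed more than any list in KO cells. The highest were Serpinb9b, a serine protease inhibitor (2.74 ± 0.1 SE, 42.9 ± 3.58 to 380 ± 58.4), Hoatz (2.34), Dner (2.14), Cox6b2 (2.07), Siglecg (2.06) and Foxs1 (1.99). Besides Hdac1 the lowest were the neutrophil-attracting chemokine Cxcl5 (-2.14 ± 0.15), Olfml3 (-1.85), Abi3bp (-1.72), Enpep (-1.65) and Acan, which encodes the cartilage proteoglycan aggrecan (-1.6). Among cell cycle regulators Cdkn2b rose by 0.81 ± 0.15, Ccnd1 by 0.64 ± 0.08, Ccnd2 by 0.76 and Rb1 by 0.66, and Cdkn2c changed by -0.77. Ccna2, which encodes cyclin A2, fell by 0.56 ± 0.15 (adjusted p = 0.0137), and Ccne1 was at 0.27 ± 0.09 (adjusted p = 0.0392). Without control replicate 1 or KO replicate 2 the adjusted p of Ccna2 was 0.062 and 0.0538. That of Ccne1 was 0.128 and 0.156 without control replicates 1 and 3, 0.0568 and 0.166 without KO replicates 2 and 3, and 0.136 after quantile normalization; it kept its call in 7 of 18 alternatives. Cdkn1b (-0.1, adjusted p = 0.355), Cdkn1c (0.2, adjusted p = 0.292) and Cdkn2a (0.09, adjusted p = 0.911) did not pass the threshold; without KO replicate 1 Cdkn1c was at 0.39 (adjusted p = 0.00651). Cdkn1b passed in 3 of 18 alternatives and Cdkn1c in 2, among them the one with +/+ cells as control (-0.3 and -1.27). Of the macrophage markers 1 of 10 passed, Csf1r (0.85).

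In all, 3234 of 13373 genes changed in KO cells, 2613 higher and 621 lower, of which 99 and 21 by 2-fold or more (71 and 31 after quantile normalization). The split was 1861 higher and 1929 lower after quantile normalization and 1624 and 2121 with centred arrays, and arrayWeights gave 1275 genes. With each array left out in turn, 1744 to 3634 were higher and 393 to 934 lower. With +/+ cells with tamoxifen as control the split was 1710 and 1515. With arrayWeights the calls of Ccna2 (adjusted p = 0.115), Chd3 (0.0696), Tk1 (0.0781), Pole (0.0674), Neu1 (0.0892) and Ccne1 (0.236) ended. With +/+ cells with tamoxifen in place of control, the calls of Tk1 (-0.48, adjusted p = 0.0764), Pole (-0.38), Ccna2 (-0.33), Neu1 (0.33), Glb1 (0.18), Ankrd1 (0.16), Mcam (0.22), Cdkn2b (0.18), Foxs1 (0.41), Csf1r (0.44), H2az1 (-0.11) and H2az2 (-0.1) ended, while Tm7sf2 (-0.27), Nsdhl (-0.02), Nr4a1 (-0.34) and Ccne1 (-0.1) changed sign. Among genes that stayed past the threshold, Serpinb9b (0.82), Cxcl5 (-0.84), Abi3bp (-0.82), Pmaip1 (0.79), Cdc25c (-0.43), Rb1 (0.25), Mt1 (0.26) and Ctsd (0.27) were closer to 0 by over 1.5 times, and Dner (3.27) and Acan (-3.41) further from it. In that comparison the calls of immediate early genes (adjusted p = 0.0686), linker histones (adjusted p = 0.234) and HDAC complex members (adjusted p = 0.211) ended, and cholesterol genes had 3 higher and 3 lower (adjusted p = 0.393). Lists that passed there but not against control were NRF2 genes (up, adjusted p = 0.00277), imprinted genes (down, adjusted p = 0.00532), senescence-associated factors (up, adjusted p = 0.0229) and matrix genes (down, adjusted p = 0.0242), with adjusted p = 0.731 for each under an estimated correlation. Against control, cartilage and acetyltransferase lists did not pass but did so, downwards, in 7 and 6 of 18 alternatives. Against these cells p53 targets had a median of 0.7 (adjusted p = 5.42e-16, and adjusted p = 0.321 with an estimated correlation), and Cdkn1a was higher by 1.33 and Mdm2 by 1.23. The medians of replication (-0.15, adjusted p = 0.0147), mitosis (-0.32, adjusted p = 4.66e-05) and lysosome genes (0.17, adjusted p = 0.0241) were closer to 0 than against control. Their adjusted p with an estimated correlation was 0.819, 0.731 and 0.731. By count, 9 of 47 replication and 11 of 49 mitosis genes fell and 0 rose, and 9 of 27 lysosome genes rose and 1 fell.

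Kd cells differed from control in 1408 genes and KO cells in 3234, an order that arrayWeights reversed (2803 and 1275). Unlike control and Kd cells, KO cells had received tamoxifen, and +/+ cells with tamoxifen differed from control in 3805 genes. These counts therefore do not rank loss of Hdac1 against knockdown of Hdac2. In Kd cells 8 of 20 cholesterol synthesis genes fell and 0 rose (13 and 0 adjusted over the list alone, median -0.27, adjusted p = 7.82e-10, and adjusted p = 0.538 with an estimated correlation), including Idi1 (-0.5) and Mvd (-0.39). Of 20 NRF2 and xenobiotic response genes 7 fell and 0 rose (8 and 0 adjusted over the list alone; adjusted p = 8.46e-06, and adjusted p = 0.681 with an estimated correlation), with Ahrr at -1.34, Gsta4 at -1.29 and Nqo1 at -1.19. Of 20 immediate early genes 10 rose and 1 fell (13 and 2 adjusted over the list alone; adjusted p = 0.000166, and adjusted p = 0.538 with an estimated correlation), led by Egr2 (1.38 ± 0.13 SE) with Junb (0.81). Stress response genes of the unfolded protein and amino acid pathways had 6 higher and 0 lower of 25 (9 and 0 adjusted over the list alone; adjusted p = 0.00158), such as Atf3 (0.76) and Ppp1r15a (0.57). Contractile genes had 7 higher and 0 lower of 20 (7 and 0 adjusted over the list alone; adjusted p = 0.00311), such as Actg2 (0.46). With an estimated correlation the adjusted p was 0.914 for both of these. Cartilage and bone genes had 1 higher, Pth1r (0.72), and 4 lower, Col2a1 (-0.58) among them, of 16 (1 and 5 adjusted over the list alone; adjusted p = 0.00299, and adjusted p = 0.538 with an estimated correlation). After quantile normalization cholesterol genes had 0 higher and 15 lower, NRF2 genes 0 and 9, and immediate early genes 10 and 2. Between +/+ cells with tamoxifen and KO cells, without a knockdown, Ahrr (-1.01), Gsta4 (-4.33), Nqo1 (-2.83), Mvd (-0.32), Egr2 (0.37), Ppp1r15a (0.3), Pth1r (0.87) and Col2a1 (-0.79) differed in the same direction as in Kd cells. Junb (-0.35) and Actg2 (-1.51) differed in the opposite one, and Idi1 (0.11) and Atf3 (-0.26) did not pass. The NRF2 list as a whole was also lower in +/+ than in KO cells (adjusted p = 0.00277, and adjusted p = 0.731 with an estimated correlation). When the knockdown was added to KO cells, Gsta4 was at 0.37, opposite to Kd against control. The other genes named in this paragraph kept their direction, Col2a1 barely (-0.1).

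Neuronal genes had 5 higher and 0 lower of 32 in Kd cells (8 and 0 adjusted over the list alone; adjusted p = 0.0453), with Stmn2 at 1.59, Tubb3 at 0.93 and Map2 at 0.84. Apoptosis regulators had 6 higher and 0 lower of 24 (6 and 0 adjusted over the list alone; adjusted p = 0.0334), such as Bcl2l11 (1.17) and Casp4 (1.03). Both had adjusted p = 0.914 with an estimated correlation. Neuronal genes kept their call in 11 of 17 alternatives that used the preset correlation; the adjusted p reached 0.106 with no filter and with only the compared groups in the model. Apoptosis regulators kept theirs in 9 of 17; the adjusted p reached 0.0865 without Kd replicate 1 and was 0.0623 after quantile normalization. Replication and mitosis genes had 0 higher and 0 lower of 47 and 49 by limma (0 and 0 adjusted over the list alone for each), with list medians of -0.07 and -0.05 (adjusted p = 0.0011 and 0.0146, and adjusted p = 0.914 for both with an estimated correlation). After quantile normalization the adjusted p of mitosis genes was 0.0554. Cdkn1a (-0.09, adjusted p = 0.604), Mdm2 (-0.09, adjusted p = 0.501; past it in 2 of 17 alternatives) and Ccna2 (-0.19, adjusted p = 0.508) did not pass the threshold, whereas Cdkn1c rose by 0.65 ± 0.13 and Cdkn2c by 0.57. Of p53 targets 4 rose, Pmaip1 (0.65) among them, and 1 fell, Perp (-1.04; 5 and 3 adjusted over the list alone). Stmn2 (1.53), Map2 (1.27), Casp4 (0.46), Cdkn1c (1.27), Cdkn2c (0.78) and Perp (-2.86) differed in the same direction between +/+ cells with tamoxifen and KO cells. Pmaip1 (-0.79) differed in the opposite one, and Tubb3 (0.04) and Bcl2l11 (-0.04) did not pass. When the knockdown was added to KO cells, Perp was at 0.84, opposite to Kd against control. The other genes named here that passed in Kd cells kept their direction.

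The highest genes in Kd cells were the chemokine Cxcl3 (21.6 ± 0.66 to 500 ± 58.7; 3.77 ± 0.1 SE), the transcription factor Foxp2 (3.63 ± 0.14), Dcn, which encodes the matrix proteoglycan decorin (3.03 ± 0.12), the coagulation inhibitor Tfpi (2.76), Pir (2.54) and Plekhb2 (2.4). Besides Hdac2 the lowest were Tmem35a (-3.56 ± 0.16), C1qtnf3 (-2.56), Pparg, the master regulator of fat cell formation (-1.82 ± 0.17), the imprinted gene Dlk1 (-1.8 ± 0.08) and Mmp23 (-1.63). Without _x_at and _s_at probe sets Dlk1 was represented by another, dim probe set and stood at 0 (adjusted p = 0.993). Slc38a4 (1.34) and Plagl1 (-0.94), also imprinted, moved in opposite directions, as did the matrix genes Lum (0.96) and Efemp1 (-1.07). In all, 1408 genes changed, 1004 higher and 404 lower, of which 80 and 48 by 2-fold or more (65 and 55 after quantile normalization). The split was 1109 and 973 after quantile normalization and 941 and 1088 with centred arrays, and arrayWeights gave 2803 genes. With each array left out in turn, 620 to 784 were higher and 259 to 343 lower. Of the genes named in this paragraph Tfpi, Pir, Plekhb2, Tmem35a, C1qtnf3 and Mmp23 also differed in the same direction between +/+ cells with tamoxifen and KO cells, which carry no knockdown, by 4.61, 2.51, 2.04, -2.92, -2.3 and -1.1. So did Slc38a4 (1.12), Lum (1.18) and, far less, Dcn (0.34, adjusted p = 0.0492), whereas Dlk1 (0.61), Plagl1 (0.39) and Efemp1 (0.29) differed in the opposite direction. Cxcl3 (0.16, adjusted p = 0.291), Foxp2 (0.34, adjusted p = 0.106) and Pparg (-0.1, adjusted p = 0.722) did not pass there. When the knockdown was added to KO cells, C1qtnf3 (0.69), Dlk1 (1.52), Plagl1 (0.6) and, barely, Efemp1 (0.09) had the opposite direction to Kd against control. The other genes named in this paragraph kept their direction there, with Cxcl3 at 0.67.

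Cells with both perturbations had lower genes of mitosis and DNA replication than control cells. All 49 mitosis and G2 genes fell (49 adjusted over the list alone; median -2.17, adjusted p = 4.48e-33), with Ncapg at -3.07 ± 0.24 SE, Spc24 at -3.03 and Nuf2 at -2.97. Of 47 replication genes 45 fell and 1 rose (45 and 1 adjusted over the list alone; median -1.61, adjusted p = 2.6e-29), with Tk1 at -3.13, Mcm10 at -2.86 and Cdc45 at -2.85. Ccna2 went from 4965 ± 491 to 1014 ± 327 (-2.31 ± 0.15). Among CDK inhibitors Cdkn1a reached 12006 ± 465 (2.09 ± 0.08), Cdkn1c went from 149 ± 15.6 to 2894 ± 209 (4.14 ± 0.13) and Cdkn2b from 149 ± 22.6 to 859 ± 181 (2.39 ± 0.15). Of 8 listed inhibitors 7 were higher and 1 lower (7 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.129; 0.0458 after quantile normalization). Of 28 p53 targets 25 rose and 1 fell (25 and 1 adjusted over the list alone; median 1.26, adjusted p = 1.77e-06), with Pmaip1 at 3.45, Tap1 at 3.19, Eda2r at 2.71 and Mdm2 at 2.29 ± 0.07. With an estimated correlation the adjusted p was 0.474 for mitosis, replication and p53 targets. The pocket protein genes moved apart, Rbl1 at -3.04 against Rbl2 at 1.92 and Rb1 at 1.36, and the cyclin gene Ccne2 was at -1.95.

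Metabolic and lysosomal groups moved as well. All 27 lysosome and autophagy genes rose (27 adjusted over the list alone; median 0.98, adjusted p = 3.47e-08), with the hydrolase genes Neu1 at 2.87, Gaa at 2.01 and Ctsd at 1.86. Of 20 cholesterol synthesis genes 17 fell and 1 rose (17 and 1 adjusted over the list alone; median -0.66, adjusted p = 2.88e-09), with Lss at -2.57, Idi1 at -1.69 and Stard4 at -1.62. With an estimated correlation the adjusted p was 0.474 for both. NRF2 and xenobiotic genes went both ways, 5 higher and 9 lower of 20 (5 and 9 adjusted over the list alone; adjusted p = 0.0271, and adjusted p = 0.7 with an estimated correlation), with Mgst1 at 7.15 against Nqo1 at -3.09 and Srxn1 at -1.94; after quantile normalization the adjusted p was 0.0721 and with centred arrays 0.0528. Genes known to rise with HDAC inhibitors had 10 higher and 1 lower of 12 (10 and 1 adjusted over the list alone; median 1.54, adjusted p = 0.00783, and adjusted p = 0.496 with an estimated correlation), including Clu (2.51) and Mt2 (2.27). Among deacetylases outside the targets Hdac11 rose by 1.79 and Hdac6 by 1.69. Of 17 acetyltransferase and bromodomain genes 3 rose and 9 fell (3 and 9 adjusted over the list alone; adjusted p = 0.0126, and adjusted p = 0.622 with an estimated correlation), with Kat2b at 1.23 and Hat1 at -0.88. Linker and replication-independent histones had 2 higher and 5 lower of 10 (2 and 5 adjusted over the list alone; adjusted p = 0.0219, and adjusted p = 0.491 with an estimated correlation), including H2ax (-1.22) and H2az1 (-0.99); this list kept its call in 14 of 18 alternatives. With +/+ cells as control the calls of the last 2 lists and of NRF2 genes ended (adjusted p = 0.0951, 0.0672 and 0.494).

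Neuronal, matrix, imprinted, contractile and pericyte lists had more genes higher than lower with both perturbations. Of 32 neuronal genes 28 rose and 0 fell (28 and 0 adjusted over the list alone; adjusted p = 0.000733, and adjusted p = 0.474 with an estimated correlation), with Uchl1 at 3.61, Crmp1 at 2.17 and Stmn2 at 2.14. Of 40 extracellular matrix genes 33 rose and 4 fell (33 and 4 adjusted over the list alone; adjusted p = 0.00224, and adjusted p = 0.622 with an estimated correlation), with Dcn at 6.7, Mfap5 at 2.15, Lum at 1.43 and Col6a2 at -1.31. Of 21 imprinted genes, expressed from 1 parental copy, 17 rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 0.00229, and adjusted p = 0.549 with an estimated correlation), with Igf2 at 8.09, Peg3 at 3.06 and Mest at 2.26. Contractile genes had 18 higher and 0 lower of 20 (18 and 0 adjusted over the list alone; adjusted p = 0.00688, and adjusted p = 0.64 with an estimated correlation), with Synpo2 at 2.26 and Lmod1 at 1.18; with centred arrays the adjusted p was 0.0503. With +/+ cells as control Lum was at 0.29 (adjusted p = 0.118). Pericyte and smooth muscle markers had 8 higher and 1 lower of 9 (8 and 1 adjusted over the list alone; adjusted p = 0.018, and adjusted p = 0.491 with an estimated correlation), with Notch3 at 5.57, Mcam at 2.85 and Rgs5 at 2.6. Endothelial markers had 6 higher and 0 lower of 7, Flt1 (1.93) and Kdr (1.53) among them, and the list did not pass (adjusted p = 0.164). Lpl (4.76) and Apoe (4.22), genes of lipid handling, rose while Pparg fell by 2.4. Icam1, an adhesion molecule, was at 3.71 and the chemokine gene Ccl2 at -2.7.

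The highest genes with both perturbations were Bex1 (21.2 ± 5.23 to 17489 ± 3390; 8.87 ± 0.16 SE), Igf2, an insulin-like growth factor of the fetus (54.5 ± 14.4 to 19085 ± 2030; 8.09 ± 0.18), Mgst1 (7.15 ± 0.09), Dcn (6.7 ± 0.12), Cox6b2 (6.55 ± 0.14) and Clca3a2 (5.97 ± 0.18). Igf2, Mgst1 and Cdkn1c were also higher in +/+ cells with tamoxifen than in control, by 3.33, 3.94 and 1.47. In KO cells, which had received tamoxifen too, these genes differed from control by 0, 0.73 and 0.2. With both perturbations against control, further dim probe sets of Mgst1 and Dcn changed by 0.01 and 0.2, and a further probe set of Igf2 by 1.44. Besides Hdac1 the lowest were S100a4, a calcium-binding protein of fibroblasts (20642 ± 267 to 948 ± 180; -4.44 ± 0.1), Aspn (-4.01), Pcolce2 (-3.88), Ifi202b (-3.56) and Styk1 (-3.28). Ccnd1 (0.59), Cdkn1b (0.39) and Ccne1 (0.37) passed the threshold. After quantile normalization Cdkn1b was at 0.15 (adjusted p = 0.0515) and Ccne1 at 0.12 (adjusted p = 0.192); they kept their calls in 16 and 15 of 18 alternatives. With +/+ cells as control the changes of Igf2 (4.77), Mgst1 (3.21), Cdkn1c (2.67), Aspn (-2.35), Uchl1 (1.53), Stmn2 (0.78), Mest (0.64), Mfap5 (0.57), Nqo1 (-0.83), Col6a2 (-0.83) and Cdkn1b (0.19) were closer to 0 by over 1.5 times and stayed past the threshold. Cdkn2a was measured at 51.3, 41.9 and 278 on the 3 arrays. Its log2 fold change of 1.06 ± 0.43 (adjusted p = 0.0415) was 0.32 (adjusted p = 0.281) without replicate 3. The adjusted p was 0.098 and 0.115 without control replicates 2 and 3, 0.154 after quantile normalization and 0.106 with +/+ cells as control; it kept its call in 8 of 17 alternatives. In all, 8755 genes changed, 6171 higher and 2584 lower, of which 1675 and 550 by 2-fold or more. The median log2 fold change of all genes was 0.161, which scaling removes: the split was 4304 and 4468 after quantile normalization and 4114 and 4675 with centred arrays, with 1165 and 858 genes by 2-fold or more after the former. After quantile normalization neuronal genes had 21 higher and 0 lower, matrix genes 28 and 7, imprinted genes 15 and 1, contractile genes 12 and 2, p53 targets 23 and 2, lysosome genes 27 and 0, and mitosis genes 0 and 49.

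**Figure D2:**
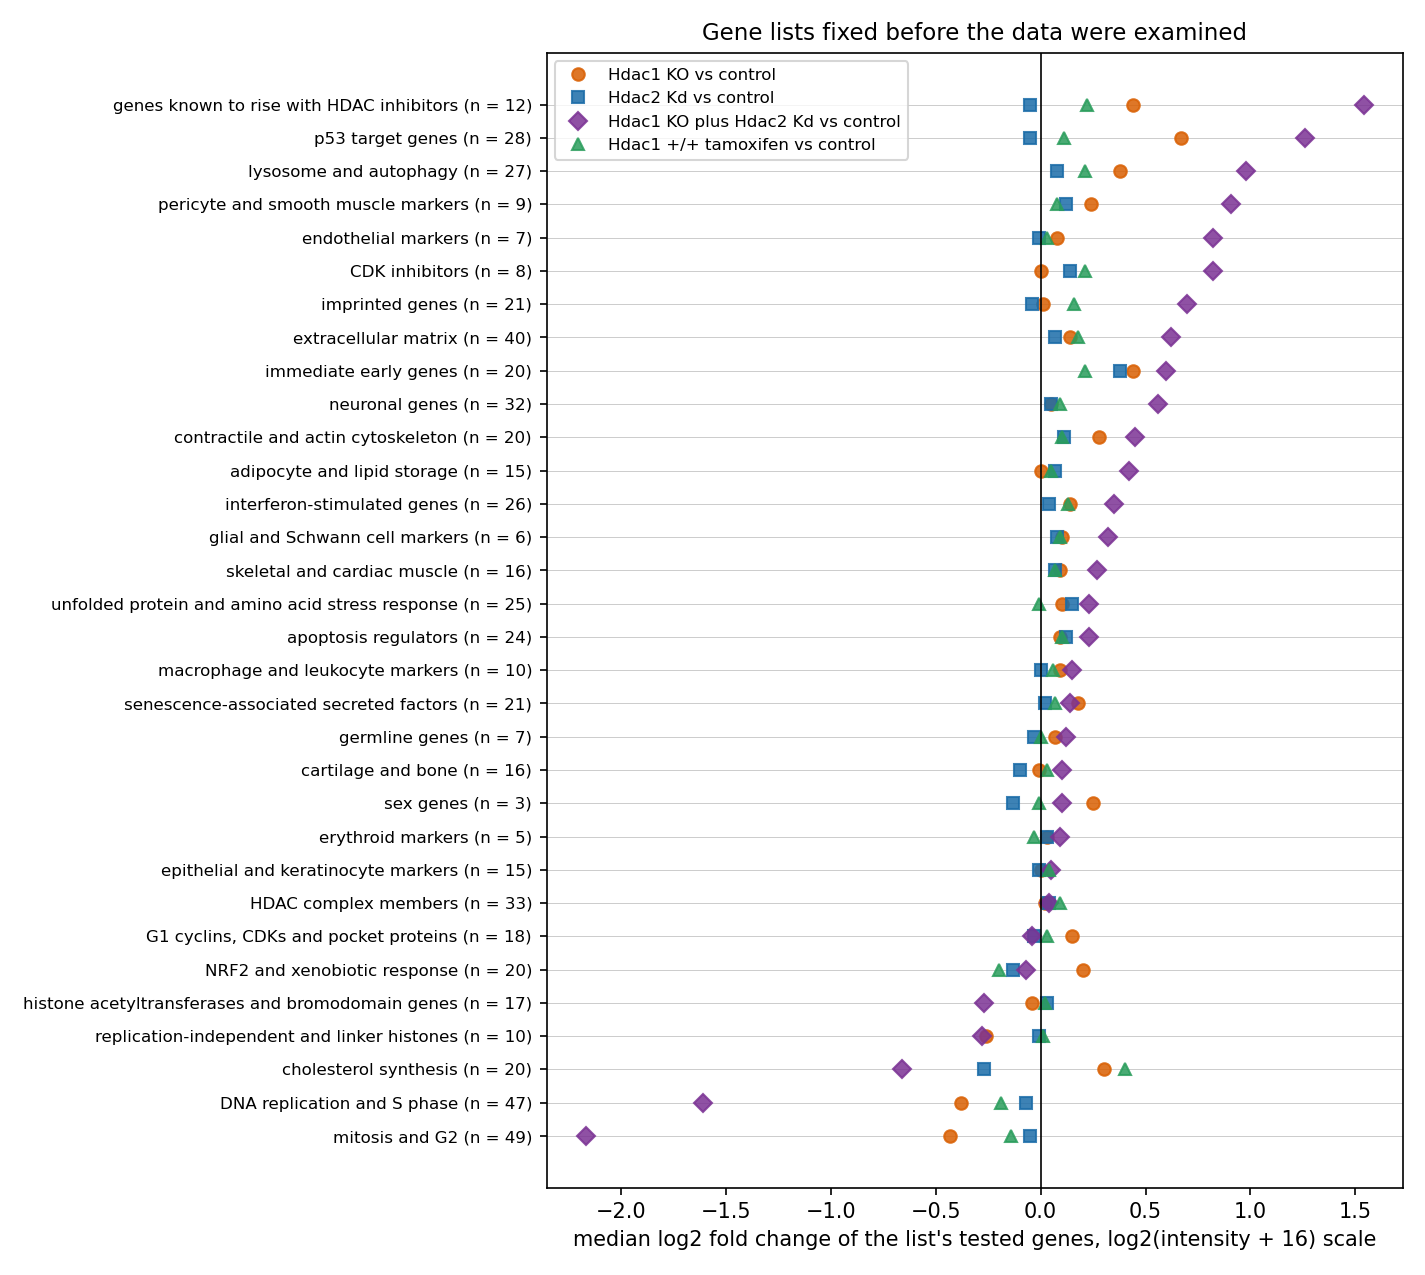
Median log2 fold change (log2(intensity + 16) scale) of the tested genes of 32 lists in 4 comparisons with control. With both perturbations mitosis genes had a median of -2.17 and p53 targets of 1.26.

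Against Kd cells, the cells with both perturbations show deletion together with tamoxifen where Hdac2 is low, since Kd cells had received ethanol. Here 5730 genes were higher and 2733 lower, 8463 in all (4182 and 4368 after quantile normalization, 4124 and 4360 with centred arrays; median of all genes 0.134). All 49 mitosis genes fell (median -2.13), among them Ncapg (-3.02) and Spc24 (-2.91). Of 28 p53 targets 23 rose and 1 fell, led by Tap1 (3.02) and Perp (2.83). Of 20 cholesterol genes 15 fell and 2 rose, led by Lss (-2.17) and Stard4 (-1.6), and all 27 lysosome genes rose, led by Neu1 (2.96) and Gaa (2.06). Adjusted over the list alone these counts were the same. The adjusted p was 9.68e-32, 4.82e-07, 2.52e-05 and 1.24e-08, and 0.484, 0.484, 0.485 and 0.484 as adjusted p with an estimated correlation. Of 21 imprinted genes 16 rose and 1 fell (adjusted p = 0.000284, and adjusted p = 0.484 with an estimated correlation), with Igf2 at 7.8, Cdkn1c at 3.49 and Dlk1 at 2.88. Rtl3 (-4.01) and S100a4 (-3.96) were the lowest besides Hdac1. Hdac3 was at 0.21 (adjusted p = 0.017), and at 0.04 (adjusted p = 0.524) after quantile normalization; the adjusted p was 0.074 without Kd replicate 3 and 0.0928 without replicate 3 of the cells with both, and the call was kept in 12 of 16 alternatives.

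Against KO cells, the cells with both differ by the micro-RNA against Hdac2 in place of the scrambled one, where Hdac1 is absent and with tamoxifen in both groups. Of 13373 genes 4831 were higher and 2762 lower, 7593 in all (4014 and 4177 after quantile normalization, 3908 and 4235 with centred arrays). All 49 mitosis genes fell (median -1.75), with Aurka at -2.6 and Ncapg at -2.55, and all 20 cholesterol genes fell (median -0.99), with Lss at -2.87 and Idi1 at -2.12. Of p53 targets 20 of 28 rose and 2 fell, with Tap1 at 2.68. Adjusted over the list alone these 3 counts were the same. The adjusted p was 5.31e-28, 5.36e-13 and 0.0024, and 0.46, 0.46 and 0.616 as adjusted p with an estimated correlation. Cdkn1c was higher by 3.95 and the imprinted gene Mest by 3.52, while S100a4 (-4.66), Nqo1 (-3.65) and Pcolce2 (-3.59) were the lowest. Hdac3 was at 0.21 (adjusted p = 0.0178), and at 0.09 (adjusted p = 0.164) after quantile normalization; without KO replicate 1 and without replicate 3 of the cells with both the adjusted p was 0.0695 and 0.0968, and the call was kept in 10 of 16 alternatives.

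The interaction tested whether deletion, given with tamoxifen, acted differently in Kd cells than in control cells. It passed for 5734 genes, 3439 with a more positive and 2295 with a more negative effect in Kd cells (3218 and 3458 after quantile normalization, 3239 and 3323 with centred arrays). Bex1 had the largest value, 7.91 ± 0.22 SE: deletion moved it by 0.19 in control and by 8.1 in Kd cells. All 49 mitosis genes and 43 of 47 replication genes had negative interactions (median -1.69 and -1.06), as had 14 of 20 cholesterol genes (18 adjusted over the list alone). Positive ones were found for 24 of 27 lysosome (25 adjusted over the list alone), 18 of 32 neuronal (19 adjusted over the list alone) and 15 of 21 imprinted genes. The adjusted p was 3.43e-27, 1.14e-21, 3.11e-09, 1.19e-07, 0.000651 and 1.96e-06 in that order, and adjusted p = 0.453 for each with an estimated correlation. Of 2225 genes changed by 2-fold or more with both, 2024 had an interaction of the same sign. Of the 8755 genes changed with both, 5329 had passed in neither single comparison, and 3087 of these had an interaction of the same sign.

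**Figure D3:**
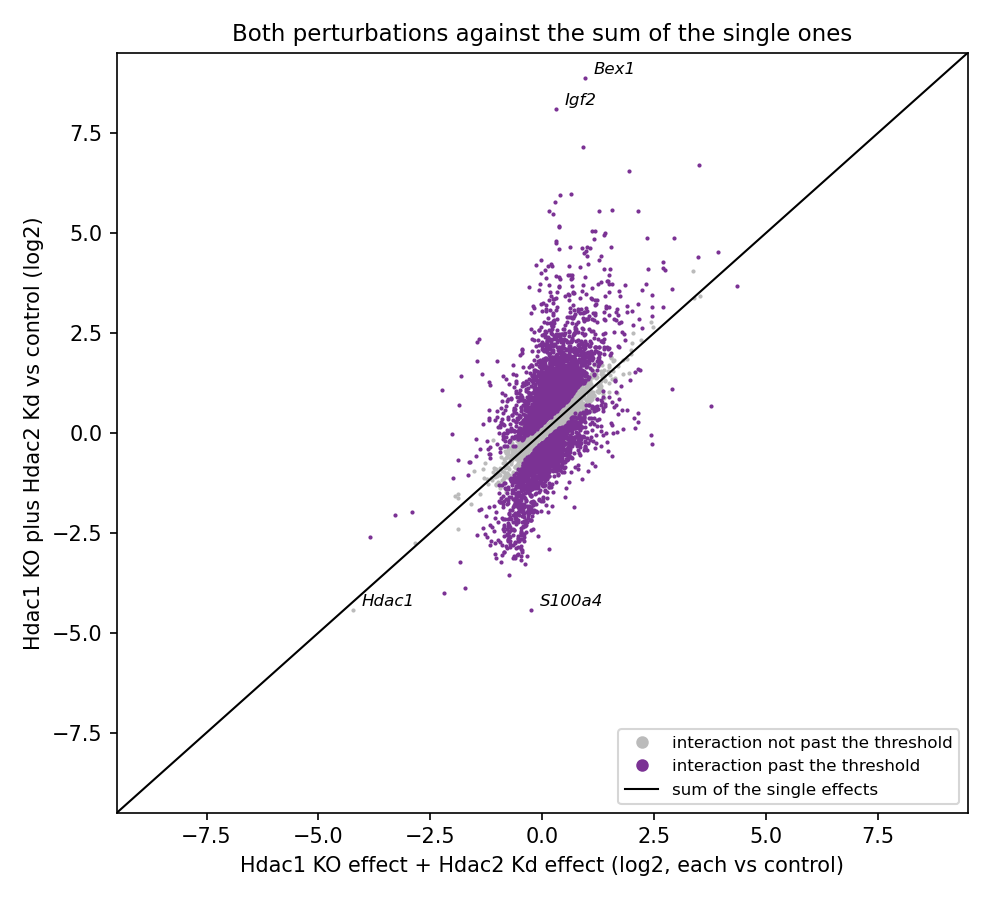
Log2 fold change of cells with both perturbations against control (vertical) and the sum of the KO and Kd log2 fold changes (horizontal) for 13373 genes; the line marks equality and coloured points passed the interaction test. Bex1 at 8.87 and Igf2 at 8.09 lie far above the line, and S100a4 at -4.44 lies below it.

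Cells with intact Hdac1 and tamoxifen differed from control in 3805 genes, 2878 higher and 927 lower (1939 and 2010 after quantile normalization, 1991 and 1901 with centred arrays), of which 175 and 103 by 2-fold or more (136 and 132 after quantile normalization). Besides tamoxifen, these cells differed from control in being +/+ in place of floxed, and possibly in their viruses. Such differences also remain where +/+ cells serve as control for other groups. The changes of +/+ cells against control can therefore not be assigned to tamoxifen alone. Cholesterol genes had 16 higher and 0 lower of 20 (16 and 1 adjusted over the list alone; adjusted p = 0.000469), led by Tm7sf2 (1.21) and Sc5d (0.68). Replication genes had 1 higher and 13 lower of 47 (1 and 13 adjusted over the list alone; median -0.19, adjusted p = 7.72e-10), led by Ung (-0.63) and Gins3 (-0.6), and mitosis genes 0 higher and 2 lower of 49 (0 and 0 adjusted over the list alone; adjusted p = 4.87e-05). NRF2 genes had 4 higher, Mgst1 (3.94) among them, and 8 lower, such as Gsta4 (-3.41) and Nqo1 (-2.26), of 20 (5 and 9 adjusted over the list alone; adjusted p = 0.00204). Lysosome genes had 14 higher and 0 lower of 27 (18 and 1 adjusted over the list alone; adjusted p = 0.00204), led by Ctsh (0.76), and imprinted genes 10 higher and 1 lower of 21 (10 and 1 adjusted over the list alone; adjusted p = 0.0197), led by Igf2 (3.33) and Nnat (2.12). Matrix genes had 20 higher and 5 lower of 40 (22 and 6 adjusted over the list alone; adjusted p = 0.0416), with Mfap5 at 1.58 and Postn at -1.38. This list kept its call in 8 of 17 alternatives; the adjusted p was 0.103 with centred arrays and 0.217 with only the compared groups in the model. With only the compared groups in the model imprinted genes had adjusted p = 0.0691. With an estimated correlation the adjusted p was 0.902 for all 7 lists. Of p53 targets 5 rose and 3 fell (6 and 3 adjusted over the list alone; adjusted p = 0.511). The highest genes were Cxcl14 (14.8 ± 1.74 to 2159 ± 135; 6.14 ± 0.1 SE), Tfpi (4.74) and Hoxa9 (4.35), and the lowest Rpl39l (5318 ± 242 to 27.6 ± 3.48; -6.94 ± 0.08), Vit (-4.32) and Cxcl1 (-3.46).

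The effects of each perturbation in both backgrounds could be compared without shared arrays. For deletion, both comparisons include tamoxifen. Of the genes changed by it in control cells 87.3% moved in the same direction in Kd cells; 2035 were called higher and 450 lower in both, against 1120 and 127 for independent lists, and 244 in opposite directions against 800 (r = 0.527 across genes). For the knockdown 75.6% moved in the same direction, with 701 higher and 190 lower in both against 363 and 83, and 220 opposite against 353 (r = 0.343). KO and Kd, which share the control arrays, had 444 genes higher and 59 lower in both against 196 and 19 for independent lists. The covariance of their fold changes was 0.0125, and 0.00496 in simulated unchanged groups. Their r was 0.19 and the simulated r was 0.5. The simulated groups held no changed genes, so the simulated r reflects shared controls alone and cannot be ranked against the measured r. KO and +/+ cells with tamoxifen had 1299 higher and 152 lower in both against 562 and 43, with a covariance of 0.0281. Kd cells, which had received ethanol, had 593 higher and 175 lower in common with +/+ cells against 216 and 28, with a covariance of 0.0351. An overlap with +/+ cells was thus seen without tamoxifen too. Part of these overlaps may come from the shared controls.

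The remaining lists did not pass camera in any of the 3 comparisons of perturbed cells with control; their counts with both perturbations were as follows. G1 cyclins, CDKs and pocket proteins had 7 higher and 7 lower of 18, interferon-stimulated genes 16 and 2 of 26, senescence-associated secreted factors 7 and 8 of 21 (8 and 8 adjusted over the list alone), adipocyte and lipid genes 10 and 4 of 15 (11 and 4 adjusted over the list alone), and skeletal and cardiac muscle genes 9 and 1 of 16. Germline genes had 3 higher and 0 lower of 7, epithelial markers 4 and 2 of 15, with Dsp at 3.95, glial markers 3 and 0 of 6, erythroid markers 1 (Epor, 0.78) and 0 of 5, macrophage markers 1 (Cd68, 0.62) and 0 of 10, and Y-linked genes 1 (Eif2s3y, 0.37) and 0 of 3. Adjusted over the list alone, the counts of the other lists were the same. With the stricter filter adipocyte genes passed with both perturbations (adjusted p = 0.0395) and epithelial markers in KO cells (adjusted p = 0.00256). After quantile normalization Cd68 was at 0.34 (adjusted p = 0.0855), and with +/+ cells as control at 0.4 (adjusted p = 0.0514).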

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

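Tests of the arrays' grouping, of the scrambled micro-RNA cells, of tamoxifen, of scaling and of dim genes were chosen after the results were seen; the interaction was planned. The effect of deletion, given with tamoxifen, differed between control and Kd cells, by the interaction, for 5734 genes. The differences were 7.91 for Bex1, 7.8 for Igf2, 6.24 for Mgst1, -4.18 for S100a4, -3.1 for Cxcl3 and -3.08 for Acta1. Among cell cycle genes they were 3.3 for Cdkn1c, 1.99 for Cdkn2b, 0.97 for Mdm2, 0.62 for Cdkn1a, 0.42 for Cdkn1b and -1.56 for Ccna2. For Hdac3 it was 0.26 (adjusted p = 0.0442), which rose above 0.05 when any of 6 arrays was left out: the adjusted p was 0.0887 and 0.106 without control replicates 1 and 2, 0.0857 without KO replicate 1, 0.0725 and 0.108 without Kd replicates 2 and 3, and 0.121 without replicate 3 of the cells with both. After quantile normalization it was 0.0629, and the call was kept in 10 of 22 alternatives. Cxcl3 moved by -0.01 with deletion in control cells and by -3.11 in Kd cells, and Acta1, an actin of skeletal muscle, by 0.64 and -2.43.

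Lists whose genes differed in the same way had median interactions of -1.69 for mitosis, -1.06 for replication, 1.03 for genes known to rise with HDAC inhibitors, 0.78 for imprinted genes, -0.64 for cholesterol synthesis, 0.62 for CDK inhibitors, 0.6 for lysosome genes, 0.51 for p53 targets, 0.36 for neuronal, 0.33 for matrix, 0.32 for adipocyte genes and -0.25 for immediate early genes. With an estimated correlation the adjusted p ran from 0.453 to 0.952 over all lists. For genes known to rise with HDAC inhibitors the adjusted p was 0.0491; the call was kept in 14 of 23 alternatives, and the adjusted p reached 0.117 without _x_at and _s_at probe sets and 0.0834 with the mean of all probe sets. For adipocyte genes it was 0.0531 with the mean of all probe sets.

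Whether chance assignment of arrays gives as many calls was counted over other groupings. For each comparison of 3 with 3 arrays there are 10 splits, too few for a share under 0.05. In each, 1 of 10 gave as many genes, the real one. The highest other split gave 1 gene for KO against a real 3234, and 0 for Kd, both, both against Kd, both against KO and +/+ cells, against real counts of 1408, 8755, 8463, 7593 and 3805. For the interaction 2 of 100 groupings of the 12 floxed arrays, the real one included, gave as many genes. The other one gave 6240 against 5734, more than the real grouping, and kept the 3 arrays with both perturbations together in 1 group, as did the next highest with 5025; 90 of the 99 others gave 0. Regrouping mixes groups that differ strongly, which widens the spread, so most other groupings give 0 with or without an interaction. In 5 data sets made without an interaction, 93 to 96 of the 99 other groupings gave 0, and so did the real grouping. The share tells against free interchange of the 12 arrays. It does not by itself exclude chance for the interaction.

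Of the 127 genes other than the target that differed by 2-fold or more between Kd and control cells, 70 also differed in the same direction between +/+ cells with tamoxifen and KO cells, which share no arrays with that comparison and have no knockdown of Hdac2 (15.1 by chance), and 23 in the opposite direction (15.6 by chance; r = 0.566). Of the 70, 25 were called in KO against control in the direction opposite to Kd, so that for these the KO cells had themselves moved. Another 34 were not called there, and 11 were called in the same direction as in Kd. A difference particular to cells with the scrambled micro-RNA, which control and KO cells carry, would also give shared genes if the +/+ cells lack it. Whether they lack it is not given in the sources used here. Such a difference of the scrambled cells may account for part of the knockdown list. As the whole cause it stays open: for 38 of the 127 genes the upper 95% limit lay under 0.5 times the knockdown effect both in +/+ against KO and in +/+ against control cells. An opposite difference of the +/+ cells would hide 1.8, 4.57 or 32.5 genes if drawn from all genes, from those 2-fold apart between both and Kd, or from those 2-fold apart from control in KO, Kd or +/+ cells. The last lies within the 95% limits of 28.1 to 49.1. Its set holds the 127 genes themselves and was chosen partly by the difference of +/+ cells from control that is scored, which can raise its value. A first bound left such differences out and was replaced after its value was seen. The 95% limits treat the 127 genes as independent draws, which genes measured on the same arrays are not. The knockdown stays open too, since 98 of the 127 (38.6 by chance), and 25 of the 38 (12.2 by chance), moved in the same direction when it was added to KO cells, which a difference of the scrambled cells also predicts, so that the explanations cannot be told apart.

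Cholesterol synthesis genes and p53 targets were both higher in KO cells, which had received tamoxifen while control cells had not. Relative to all genes, the cholesterol list had a median of 0.22 in KO and 0.32 in +/+ cells with tamoxifen against control, and -0.1 in KO against +/+ cells (adjusted p = 0.393), so that tamoxifen or another difference of tamoxifen-treated cells may account for its rise. The p53 list had a median of 0.03 in +/+ cells and of 0.7 in KO against +/+ cells (adjusted p = 5.42e-16; adjusted p = 0.321 with an estimated correlation), which argues against tamoxifen alone. Loss of Hdac1 and activity of Cre recombinase in floxed cells both stay open. The +/+ cells had intact Hdac1, but whether they carried Cre-ERT2 is not given in the sources used here.

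More genes were higher than lower with both perturbations: 70.5% of all calls, and 3.05 times as many among calls of 2-fold or more. After quantile normalization 49.1% of all calls were higher, a value that scaling to a common distribution fixes, so that scaling and a real global rise cannot be told apart. The ratio among 2-fold calls was 1.36 after quantile normalization and 1.32 with centred arrays, so scaling stays open for these as well. Dim genes have little room to fall. Among genes whose mean over all arrays was below the 60th percentile, 339 were higher and 4 lower by 2-fold or more. By count these genes added to the imbalance, but how much of it the floor accounts for stays open. Among genes above that percentile the ratio was 1.08 after quantile normalization and 2.45 without. That split was first made with the mean of the control arrays (0.93 and 2.18) and, like the reading of the test, was changed after values were seen; both splits use arrays of the comparison itself, so that neither decides.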

How the results depend on the processing

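Alternatives were fixed before the data were examined, and none was added. Of 7 counts of changed genes, 1 alternative moved 2 by more than 1.5 times: arrayWeights gave 1275 genes for KO in place of 3234 and 2803 for Kd in place of 1408; the cause was not tested. With each array left out in turn the counts ran from 2359 to 4027 for KO, 953 to 1046 for Kd, 8199 to 8371 for both, 7805 to 8033 for both against Kd, 7078 to 7618 for both against KO, 5195 to 5884 for the interaction and 2802 to 3351 for +/+ cells. With the replicate block they were 3000, 1298, 8599, 8322, 7451, 5509 and 3543. Same-numbered arrays did not deviate together (r from -0.16 to 0.136, 4 of 30 pairs above 0.1; 3 of 15 arrays correlated best with their own number), so the numbers are not taken as pairs. With +/+ cells as control KO had 3225 genes, 1429 of them shared with the 3234, and both had 8250. The correlation between backgrounds, 0.527 for deletion, was 0.526 without a filter and 0.531 over called genes; for the knockdown 0.343 became 0.345 and 0.353. Results that changed sign were, with +/+ cells as control, Cdkn1c (-1.27), Ccne1 (-0.1), Tm7sf2 (-0.27), Nsdhl (-0.02) and Nr4a1 (-0.34) in KO, the matrix list (adjusted p = 0.0242) and the cholesterol list (adjusted p = 0.393) in KO, and Ccne1 with both (0). Dlk1 in Kd was at 0 without _x_at and _s_at probe sets, where another probe set stands for the gene; the other causes were not tested. Over the 243 values of named genes, 4170 alternative values kept direction and side of the threshold, 31 had the opposite direction with no call in either setting, 80 lost the call, 12 gained one and 7 changed sign. Over the lists the numbers were 3992, 86, 126, 54 and 2. Signal over background limits dim genes: at intensities near 20, changes on the log2(intensity + 16) scale are understated.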

Other observations

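Gene families in this part were chosen after their values were seen, and members that only shared a name were removed later, so their tests are descriptions of these arrays. All 4 tested Bex genes, X-linked genes named for their expression in brain, were higher with both perturbations, Bex1 by 8.87, Bex2 by 5.55, Bex4 by 2.2 and Bex3 by 1.08 (camera adjusted p = 0.00349, and adjusted p = 0.139 with an estimated correlation). Of 16 H2 histocompatibility genes, B2m, Tap1, Tap2 and Tapbp, several of which serve antigen presentation, 10 were higher and 0 lower, with Tap1 at 3.19, H2-D1 at 2.33, H2-K1 at 2.07, Tapbp at 1.73 and B2m at 0.95 (adjusted p = 0.00478, and adjusted p = 0.139 with an estimated correlation; 10 and 0 after quantile normalization). Tap1 is also in the list of p53 targets. Of 30 Wnt ligands, receptors and secreted inhibitors 19 were higher and 1 lower, with Sfrp1 at 4.61, Dkk2 at 3.2 and Wnt5b at 3.09 (adjusted p = 0.0111, and adjusted p = 0.289 with an estimated correlation; 17 and 3 after quantile normalization). Of 37 collagen genes 25 were higher and 3 lower (adjusted p = 0.00483, and adjusted p = 0.195 with an estimated correlation; 20 and 7 after quantile normalization). Of 18 Hox genes 4 were higher and 3 lower with both perturbations (adjusted p = 0.604, and adjusted p = 0.91 with an estimated correlation), with Hoxb4 at 1.99 and Hoxa7 at -1.13. The counts of Hox genes were 2 and 4 after quantile normalization and 2 and 6 with centred arrays. In KO cells 0 were higher and 3 lower, with Hoxa7 at -0.88 (adjusted p = 0.0197, and adjusted p = 0.767 with an estimated correlation).

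Ribosomal protein and mitochondrial respiratory genes depended on scaling. With both perturbations 27 of 44 genes of ribosomal proteins and their paralogs were higher and 4 lower, but 2 higher and 12 lower after quantile normalization and 2 and 18 with centred arrays. Of 63 subunit genes of complexes I, IV and V 36 were higher and 6 lower, but 20 and 19 after quantile normalization and 11 and 21 with centred arrays. No direction is given for either family.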
